A study of Rattus norvegicus with 9 samples.

How the data were processed

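RNA of rat brain was hybridised to Clariom D rat arrays in 9 samples: 3 of parietotemporal cortex of sham rats, 3 of hippocampus of sham rats and 3 of hippocampus after TFS. The labels give total RNA from male rats killed by decapitation, dissection in the cold, frozen storage, labelling with biotin using the GeneChip WT Plus kit, and no technical replicates. The deposited values are on the log2 scale, 1 per transcript cluster or control probe set. The submitters' processing notes name RMA and limma without version or order. Values ran from 1.07 to 13.6 with nearly equal quartiles on every array, as RMA with quantile normalization across arrays leaves them. The genome build and the annotation version are not given in the sources used here, so no positions are printed. Arrays have no read depth: their number limits the precision, and signal over background is given as the distance between positive and negative control probe sets.

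Of 70580 rows in the table, 1738 control rows were left out, leaving 68842 transcript clusters. The platform annotation gave 1 gene symbol for 23446 rows, several for 505 and none for 44891; 22077 rows had an Entrez identifier found in the RefSeq gene table, through which 1 symbol was updated. Rows with 1 symbol gave 22093 genes, and for the 1182 genes with more than 1 row the row with the highest mean was used. Genes with a mean at or above the median of all row means (4.99) were tested, 15522 in all. Median polish leaves the same value on several arrays for many genes: 11445 tested genes share a value exactly between at least 2 arrays, 8554 between at least 3, and 97 have 1 value on all 9. Bdnf and Abcb1a share a value between 6 arrays.

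One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 1.46 prior degrees of freedom), with contrasts of TFS minus sham in hippocampus and of hippocampus minus cortex in sham rats. Tests are two-sided, and p-values are adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. An exact test of 3 against 3 arrays cannot go below 0.1. P-values measure the spread between these samples, since the labels do not say that each array is a separate animal. Gene lists, 40 in all, were tested with camera (preset correlation 0.01) and with its estimated correlation, and with fry, which tests a shift in one direction and, as a mixed test, a change in either direction. Of these, 38 had enough tested members. No mitochondrially encoded transcript was matched on the array, so that list was not analysed here, and the list of olfactory receptors was counted before the filter on signal. Members without a row are counted as not measured and are not analysed here. Older symbols were matched through RefSeq synonyms. Counts "adjusted over the list alone" correct for the members of that list only.

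The genes named are the 10 with the largest log2 difference in each direction among genes past the threshold whose arrays do not overlap or, where none passed, the 10 with the smallest p in each direction; up to 4 members with the smallest p of each list described; and a fixed set of genes, 18 of them measured, followed as values. The design, the lists, this rule and most alternatives were set before the data were examined; exceptions are stated where they appear. The fit was tested on simulated data made from 15522 genes with 200 changed genes.

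Whether arrays of one number belong together was checked from their deviations from the group means. Across genes, cortical and hippocampal sham arrays of one number correlated at 0.416, 0.202 and 0.252, against -0.291 to 0.0604 for unlike numbers. Deviations from a group mean cancel within the group, so a positive value for like numbers forces lower ones for unlike numbers. The contrast is therefore partly built in and does not show pairing. Pairs by number were used in alternative fits, not in the main fit. TFS and sham hippocampal arrays of one number correlated at -0.111, -0.287 and -0.025 and were not paired. For TFS and sham hippocampal arrays of unlike numbers the correlations ran from -0.134 to 0.264. The highest lay above the 0.202 and 0.252 of the sham arrays numbered 2 and 3, so values of that size alone do not show pairing.

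The alternatives were other filters on signal (none, and the 75th percentile), every row whether named or not, the mean of all rows of a gene, the 6 arrays of a comparison alone, median centring, quantile normalization of tested genes, eBayes with trend and robust options, array weights, the number as a fixed or random block, an adjusted p under 0.1, an unadjusted p under 0.05 with at least a 1.5-fold difference, principal components of the 1000 tested genes of largest variance, and leaving out each array in turn. Chosen after seeing the data were a block over the 6 sham arrays only, leaving out both sham arrays numbered 1, leaving out genes with a value shared by 3 or more arrays, and quantile normalization before the list tests. The ranges of adjusted p given for single genes and for lists come from refits of those values with the preset correlation. They leave out the 75th percentile filter, trend and robust options, array weights and the random block, which were run for counts of genes; those of genes also leave out quantile normalization and the fit without shared values, and those of lists the mean of all rows. A fit that leaves out 1 array keeps at least 2 in each group.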

Results

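Gene expression was measured with Clariom D rat arrays in brain tissue of male rats. Transcranial focal stimulation (TFS), a current passed through the scalp, was given at 300 Hz and 50 mA for 5 min, and tissue was taken 4 h later. Sham rats went through a sham manipulation. The 9 arrays form 3 groups of 3: bilateral parietotemporal cortex of sham rats, bilateral hippocampus of sham rats, and bilateral hippocampus after TFS. The cortex of stimulated rats is not among the deposited arrays, so an effect of TFS was compared in hippocampus alone. Array medians lay between 4.95 and 5.04 on the log2 scale, and positive control probe sets lay at least 3.67 log2 units above negative ones on every array. This distance was 3.73, 3.80 and 3.96 on hippocampal sham arrays 1, 2 and 3 and at least 3.95 on the TFS arrays. Of the negative control probe sets 95% had a mean under 7.57. Lower signals are called within the background range here, as they are for 11056 of the 15522 tested genes. The limit is the upper end of the negative controls, whose medians lay between 4.055 and 4.213 on the 9 arrays. A signal under it is therefore not shown to be background alone. The log2 differences given are differences of array signal. Where a level lies in the background range they give the direction and size of the signal difference and do not measure the ratio of transcript. The number of arrays limits the precision.

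The arrays separated by brain region and not by treatment. The first principal component of 15522 tested genes held 67.9% of the variance and set the 3 cortical arrays apart from the 6 hippocampal ones. Pearson correlations across genes were 0.995 to 0.997 between sham and TFS hippocampus, inside the range of 0.994 to 0.998 found within groups, and 0.977 to 0.986 between cortex and hippocampus. Genes are not independent replicates. The second component held 8.96% and set apart the cortical and the hippocampal sham array that both carry number 1.

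The first comparison asks which genes differ in the hippocampus of healthy rats 4 h after TFS. No gene passed the test: limma called 0 of 15522 genes at an adjusted p under 0.05, and 805 genes had an unadjusted p under 0.05, where chance alone gives 776.1. Differences were small, with a median size of 0.031 log2 units. The 95% confidence interval excluded a 1.5-fold difference in either direction for 99.2% of the genes and a 1.2-fold difference for 87.5%. For the 4466 genes with a mean above the background range, a group set apart after the results were seen, these shares were 99.3% and 84.9%. The shares take no account of values shared exactly between arrays, as 8554 tested genes have between at least 3. Where median polish makes arrays equal the interval can be too narrow, so the shares may overstate what is excluded. Of these 4466 genes 457 had an unadjusted p under 0.05 by limma, a larger share than the 5.19% among all tested genes. Among the 457 genes 447 were higher, and 0 passed at an adjusted p under 0.05. The immediate early genes Fos and Egr1, transcription factors that neuronal activity induces, were not higher 4 h after stimulation: both had lower values on all 3 TFS arrays than on any sham array, without passing the test. The Fos signal lay within the background range in every group, which limits what it shows about the transcript. Tissue was taken at 4 h only, so an earlier rise of these genes could not be seen.

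Fos measured 5.62 ± 0.025 (SD, n = 3, log2) in sham and 5.36 ± 0.029 (SD, n = 3) in TFS hippocampus, a difference of -0.26 (SE 0.10, adjusted p = 0.923). The cortical sham level of Fos was 6.17 ± 0.23 (SD, n = 3). For Egr1 the difference was -0.18 (SE 0.09, adjusted p = 0.923), from a sham level of 8.43 ± 0.051 (SD, n = 3). Arc, which encodes a synaptic protein made after activity, differed by -0.07 with all TFS arrays below all sham arrays (adjusted p = 0.975). Npas4, another activity-induced transcription factor, differed by -0.12 with overlapping arrays (adjusted p = 0.923). The fit pools the spread of all 9 arrays, and the SD of Arc was 0.346 in cortex, 0.029 in sham and 0.016 in TFS hippocampus. The SE and p of Fos, Egr1 and Arc therefore largely reflect the spread in cortex. Across the alternatives the adjusted p of Fos ranged from 0.134, in a fit of the 6 hippocampal arrays alone, to 1. Of the 24 immediate early genes measured, 0 passed the test over all genes by limma, 0 did when adjusted over the list alone, and 1, Fos, had an unadjusted p under 0.05. As a list they did not pass (camera adjusted p = 0.312, tested lower), with a median difference of 0.02 and a mean of -0.0067, which differ in sign. The 26 later activity-regulated genes, such as the secreted growth factor Bdnf at 0.00 (adjusted p = 1), did not pass either (adjusted p = 0.688, tested lower, with a median of 0.0031 and a mean of 0.01 above 0). The signals of Npas4 and Bdnf, like that of Fos, lay within the background range in every group, which limits what they show about the transcripts.

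No gene for inhibitory or excitatory transmission passed the limma test. Gad1 and Gad2, which encode the enzymes that make GABA, differed by 0.09 and -0.00023 (adjusted p = 0.923 and 1), and the 18 genes for GABA synthesis, transport and receptors did not pass as a list (median 0.05, adjusted p = 0.500). The vesicular glutamate transporter Slc17a7 differed by 0.04 (adjusted p = 0.957). The 27 glutamate receptor and transporter genes had a median of 0.03 (camera adjusted p = 0.395), with 4 members higher and 1 lower at an unadjusted p under 0.05. By fry's mixed test, which asks for changes in either direction, they passed (adjusted p = 0.0456). Abcb1a, a drug efflux pump of the blood-brain barrier, differed by 0.08 (adjusted p = 0.923), and the 11 drug efflux transporters had a median of 7.5e-04 and a mean of 0.02 but tested lower (adjusted p = 0.904). Markers of glial reaction showed no call: Gfap of astrocytes differed by -0.02 (adjusted p = 1) and Aif1 of microglia by -0.03 (adjusted p = 0.923). The signals of Aif1 and Abcb1a lay within the background range in every group, which limits what they show about the transcripts. Inflammatory mediators (adjusted p = 0.922), reactive astrocyte genes (adjusted p = 0.910) and apoptosis regulators (adjusted p = 0.874) had list medians of 0.02, 0.02 and 0.01, although reactive astrocyte genes tested lower than other genes. All 3 of these lists had 0 members past the limma test, with 1, 0 and 0 members at an unadjusted p under 0.05.

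Several neuronal and metabolic gene lists lay higher than other genes by small amounts. With camera's preset correlation, 11 of 38 lists passed, 8 higher and 3 lower; with an estimated correlation 0 passed, and fry called 0 lists for a shift in one direction. Presynaptic vesicle genes had a median of 0.07, 25 of 26 members above 0 and all 3 TFS arrays on that side (adjusted p = 0.0013 with the preset, adjusted p = 0.857 with an estimated correlation). None of them passed over all genes and 1 did when adjusted over the list alone, the synaptic vesicle protein Sv2c at 0.15; the synapsins Syn2 and Syn1 lay at 0.13 and 0.12. General neuron markers had a median of 0.07 (adjusted p = 0.0196, and adjusted p = 0.857 with an estimated correlation), with Stmn2 at 0.14 and Nrgn at 0.10. Postsynaptic scaffold and kinase genes had a median of 0.04 (adjusted p = 0.0219, and adjusted p = 0.857 with an estimated correlation), with Cacng3 at 0.23, and circadian clock genes a median of 0.06 (adjusted p = 0.0251, and adjusted p = 0.857 with an estimated correlation), with the clock output genes Dbp and Hlf at 0.27 and 0.24 and the clock activator Bmal1 at -0.11. Astrocyte markers (median 0.04, Gpr37l1 at 0.14, adjusted p = 0.0219), heat shock and unfolded protein genes (median 0.07, adjusted p = 0.0251), oxidative phosphorylation subunits (median 0.03, adjusted p = 0.0423) and housekeeping genes (median 0.05, adjusted p = 0.0431) also passed with the preset, each at adjusted p = 0.951 with an estimated correlation. In the heat shock list 1 of 24 members, the transcription factor Xbp1 at 0.21, passed when adjusted over the list alone, and 0 passed over all genes.

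Most of these list calls depended on scaling and on single arrays. The median difference of all genes went from -0.0096 in the dimmest of 10 equal groups by signal to 0.05 in the brightest. After quantile normalization of the tested genes 0 of the lists passed, and the medians of postsynaptic genes, oxidative phosphorylation subunits and housekeeping genes turned to -0.0020, -0.013 and -0.0037. Those of heat shock, clock, neuron, presynaptic and astrocyte lists stayed above 0, at 0.048, 0.034, 0.028, 0.014 and 0.0038 (adjusted p = 0.0764, 0.0857, 0.626, 0.532 and 0.771). The number of lists past the threshold was 2 without hippocampal sham array 1, 2 without TFS array 1, 5 without TFS array 2, 7 without TFS array 3, 8 without sham array 3 and 10 without sham array 2. Presynaptic genes passed whichever 1 of the 6 hippocampal arrays was left out (adjusted p at most 0.0339 with the preset). With an estimated correlation they passed in no refit (lowest adjusted p = 0.478). Without sham array 1 the adjusted p was 0.0910 for neuron markers, 0.330 for postsynaptic genes, 0.180 for clock genes, 0.168 for astrocyte markers, 0.199 for heat shock genes, 0.738 for oxidative phosphorylation and 0.644 for housekeeping genes. Without TFS array 1 it was 0.0575 for postsynaptic, 0.0949 for clock and 0.0728 for housekeeping genes and 0.0629 for astrocyte, heat shock and oxidative phosphorylation genes. Without TFS array 2 it was 0.0525 for astrocyte and oxidative phosphorylation genes, 0.180 for heat shock genes and 0.0725 for housekeeping genes. Without TFS array 3 it was 0.0503 for neuron, postsynaptic and clock genes, 0.158 for oxidative phosphorylation and 0.0677 for housekeeping genes. Without sham array 3 it was 0.0607 for neuron markers, 0.117 for clock genes, 0.0804 for astrocyte markers and 0.0523 for housekeeping genes, and without sham array 2 it was 0.0847 for heat shock genes. Over 13 refits with the preset correlation the adjusted p ranged from 8.03e-05 to 0.532 for presynaptic genes, from 7.90e-04 to 0.626 for neuron markers, from 0.0021 to 0.999 for postsynaptic genes and from 0.0031 to 0.225 for clock genes. The ranges were 0.0016 to 0.771 for astrocyte markers, 4.63e-04 to 0.297 for heat shock genes, 0.0032 to 0.771 for oxidative phosphorylation and 0.0108 to 0.958 for housekeeping genes.

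The 3 lists that tested lower were markers of red blood cells, of choroid plexus and ependyma, and of leukocytes. Whether dissection accounts for the blood cell lists was not tested. Red blood cell genes had a median of -0.09 over 7 members (adjusted p = 0.0423, and adjusted p = 0.951 with an estimated correlation), with the haemoglobin gene Hbb-b1 at -0.66. Choroid plexus and ependyma markers had a median of -0.04 (adjusted p = 0.0431, and adjusted p = 0.951 with an estimated correlation), and 1 of the 3 TFS arrays lay on that side. Leukocyte markers had a median of -0.04 (adjusted p = 0.0431, and adjusted p = 0.890 with an estimated correlation), with Cd79b at -0.08. Each of these calls depended on single arrays and on the processing. Without a filter on signal the camera adjusted p with the preset was 0.245 for choroid plexus, 0.299 for red blood cell and 0.0674 for leukocyte lists. In the same order it was 0.0550, 0.0512 and 0.0550 in the 6 hippocampal arrays alone, and 0.244, 0.110 and 0.0724 after median centring. The choroid plexus median turned to 0.08 without TFS array 3 (adjusted p = 0.397) and to 0.02 without sham array 3 (adjusted p = 0.697), and was -0.12 without TFS array 2 (adjusted p = 3.92e-05) and without sham array 2 (adjusted p = 0.0180). Without sham array 1 or TFS array 1 it was -0.053 and -0.075 (adjusted p = 0.0773 and 0.0575). The red blood cell median turned to 0.06 without sham array 3 (adjusted p = 0.843) and was -0.40 without sham array 1 (adjusted p = 4.74e-05). Without sham array 2 the adjusted p of red blood cell genes was 0.147, and without TFS array 1, 2 or 3 it was 0.0629, 0.0538 and 0.158, the last at a median of -0.034. The leukocyte median was 0 without sham array 1 (adjusted p = 0.738), -0.0010 without TFS array 1 (adjusted p = 0.192) and -0.038 without TFS array 2 (adjusted p = 0.0525). Over 13 refits with the preset correlation the adjusted p ranged from 3.92e-05 to 0.697 for choroid plexus markers, from 6.80e-07 to 0.843 for red blood cell genes and from 0.0188 to 0.738 for leukocyte markers. No member of the 3 lists passed the limma test over all genes or adjusted over the list alone, and 1, Cd79b, had an unadjusted p under 0.05.

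The genes with the smallest p-values changed little. Tspy26 was 6.69 ± 0.022 (SD, n = 3) in sham and 6.88 ± 0.012 (SD, n = 3) in TFS hippocampus, a difference of 0.19 (SE 0.018, adjusted p = 0.179). Gstm6, a glutathione transferase gene, differed by 0.35 (SE 0.038, adjusted p = 0.188), and the transcription factor gene Nhlh1 by 0.48 (SE 0.076, adjusted p = 0.567). Polr1e, Atp6v1a, Zfp972, Dnajc12, Sgpp2, Mas1 and Mtarc2 differed by 0.12 to 0.38, all at adjusted p = 0.567. In each of these 10 genes all TFS arrays lay above all sham arrays. On the lower side Sln, which encodes the calcium pump regulator sarcolipin, differed by -0.24 (adjusted p = 0.661), Otof by -0.19 (adjusted p = 0.763) and Zmynd12 by -0.09 (adjusted p = 0.567), with all TFS arrays below all sham arrays. The largest differences at an unadjusted p under 0.05 were 0.81 for Nat8f3 (SE 0.19, adjusted p = 0.698), 0.59 for Acsm5 (SE 0.18, adjusted p = 0.824) and -0.86 for Sncg (SE 0.31, adjusted p = 0.921), 3 genes named after their values were seen. Sncg was 7.06 on sham array 1, and 8.17 on sham arrays 2 and 3.

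Among the 805 genes with an unadjusted p under 0.05, 679 were higher and 126 lower (84.3% higher); after centring each array on its median 63.6% were higher, and after quantile normalization 56.8%. Over every row, named or not, the split was the other way, 736 higher and 983 lower (42.8% higher). Among the 4466 genes above the background range 447 were higher and 10 lower. The TFS and sham arrays did not overlap for 1517 genes, 9.77%. Chance gives 10% for genes without shared values, and less where groups share a value, which counts as overlap. The share of 9.77% can therefore not be read as at or below chance.

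**Figure D1:**
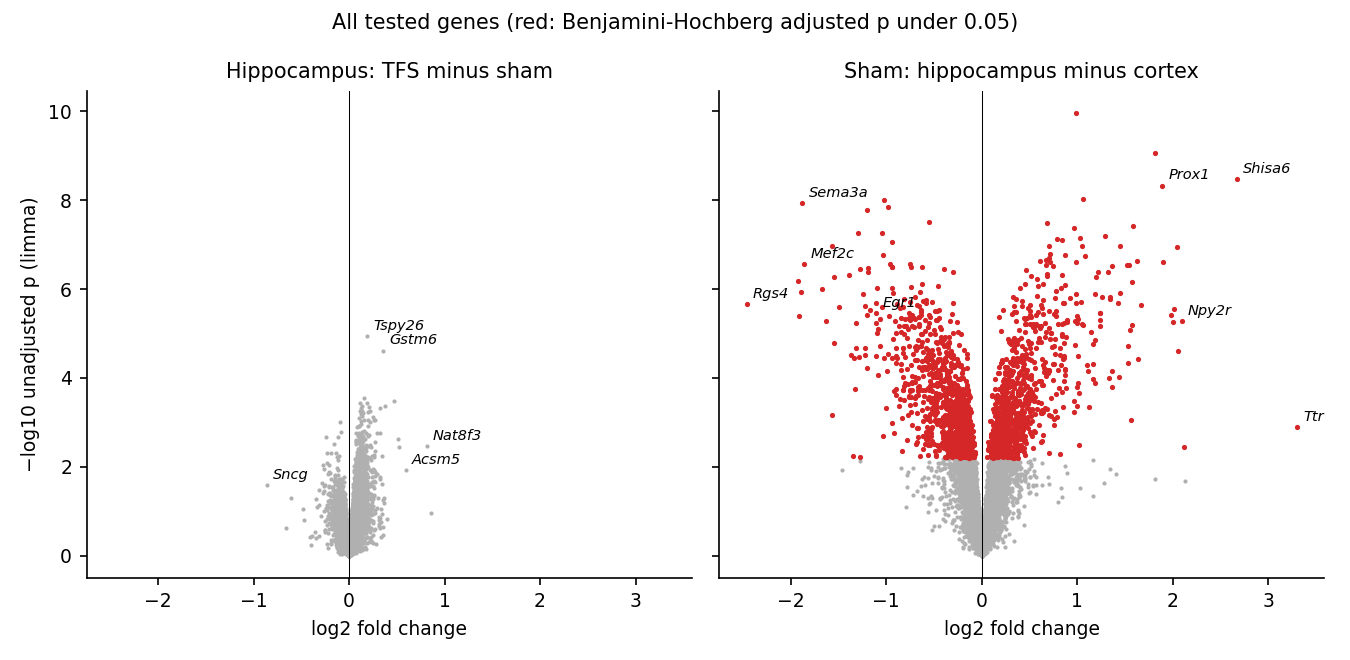
Log2 fold change against the limma p-value (negative log10, unadjusted) for 15522 tested genes, TFS minus sham hippocampus on the left and sham hippocampus minus sham cortex on the right, 3 arrays a group. Red points passed an adjusted p under 0.05: 0 genes on the left and 1931 on the right.

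The second comparison asks how hippocampus and parietotemporal cortex differ in sham rats. Of 15522 genes 1931 passed the test, 929 higher and 1002 lower in hippocampus, and 116 of these differed by over 2-fold. With camera's preset correlation, lists of dentate gyrus and CA field genes, myelin and oligodendrocyte precursor genes and choroid plexus genes tested higher in hippocampus; with an estimated correlation 0 lists passed. Lists of cortical layer genes, immediate early genes, clock genes, neuropeptides and meningeal and endothelial markers tested lower with the preset, and none of them passed with an estimated correlation. Sham arrays of one number deviated together across the regions, which does not show that they pair, and the main fit took no pairs. A fit that takes them as pairs called 982 genes, 500 higher and 482 lower, of which 866 are among the 1931. This paired fit holds the 6 sham arrays alone; the same 6 arrays without the pairs called 1211, so the lower count is not due to pairing alone. Fos, Rorb, Ndst4 and Mobp, described further on as losing their call in the paired fit, did not pass in the 6 arrays without pairs either (adjusted p = 0.0572, 0.0743, 0.106 and 0.0730).

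Shisa6, a gene for an auxiliary subunit of AMPA receptors (Entrez Gene 497926), was 7.07 ± 0.17 (SD, n = 3) in cortex and 9.75 ± 0.065 (SD, n = 3) in hippocampus (log2 difference 2.67, SE 0.085, adjusted p = 1.72e-05). Prox1 (Entrez Gene 305066), a transcription factor of dentate granule cells, was 6.07 ± 0.034 (SD, n = 3) in cortex and 7.96 ± 0.14 (SD, n = 3) in hippocampus (log2 difference 1.89, SE 0.063, adjusted p = 1.82e-05). Npy2r, a neuropeptide Y receptor, Htr5b, a serotonin receptor, the desmosomal gene Pkp2, the calcium-binding protein gene Cabp7, the sodium-proton exchanger Slc9a4, Lrrc10b and Cpne4 were higher by 1.90 to 2.10 log2 units. Ttr, which encodes the thyroid hormone carrier transthyretin, differed by 3.30 (SE 0.66, adjusted p = 0.0161), and Ndst4, a heparan sulfate enzyme gene, differed by 2.12 (SE 0.51, adjusted p = 0.0335). In each of these genes all 3 hippocampal sham arrays lay above all 3 cortical arrays. The cortical means of all of them but Cabp7 lay under 7.57, within the background range, and Cabp7 lay at that level. Ttr did not pass without cortical array 1 (adjusted p = 0.0586) or hippocampal array 3 (adjusted p = 0.0634), and ranged from 0.0077 to 0.115 over the alternatives. Ndst4 did not pass without hippocampal array 1, 2 or 3 (adjusted p = 0.0820, 0.106 and 0.0947) or with the paired fit (adjusted p = 0.121), over a range of 0.0102 to 0.121.

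Rgs4, a brake on G protein signalling (Entrez Gene 29480), was 10.6 ± 0.16 (SD, n = 3) in cortex and 8.13 ± 0.32 (SD, n = 3) in hippocampus, a log2 difference of -2.46 (SE 0.19, adjusted p = 2.99e-04). The transcription factor Mef2c differed by -1.86, the axon guidance gene Sema3a by -1.88 and the potassium channel gene Kcnh5 by -1.91. Tmem196, the neurturin receptor gene Gfra2, Car10, Exph5, Ephx4 and Cd34 differed by -1.92 to -1.56. In each of these 10 genes all hippocampal arrays lay below all cortical arrays. The means of Sema3a and Exph5 lay under 7.57, within the background range, in both regions. Those of Kcnh5, Tmem196, Gfra2, Ephx4 and Cd34 did so in hippocampus. Of the cortical layer genes followed throughout, Cux2 differed by -0.90 (SE 0.078, adjusted p = 4.34e-04) and Rorb by -0.61 (SE 0.13, adjusted p = 0.0221). Rorb did not pass without cortical array 1 (adjusted p = 0.0563), cortical array 2 (0.0564), hippocampal array 1 (0.0702) or hippocampal array 2 (0.0743), or in the paired fit (adjusted p = 0.154), over a range of 0.0074 to 0.154.

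**Figure D2:**
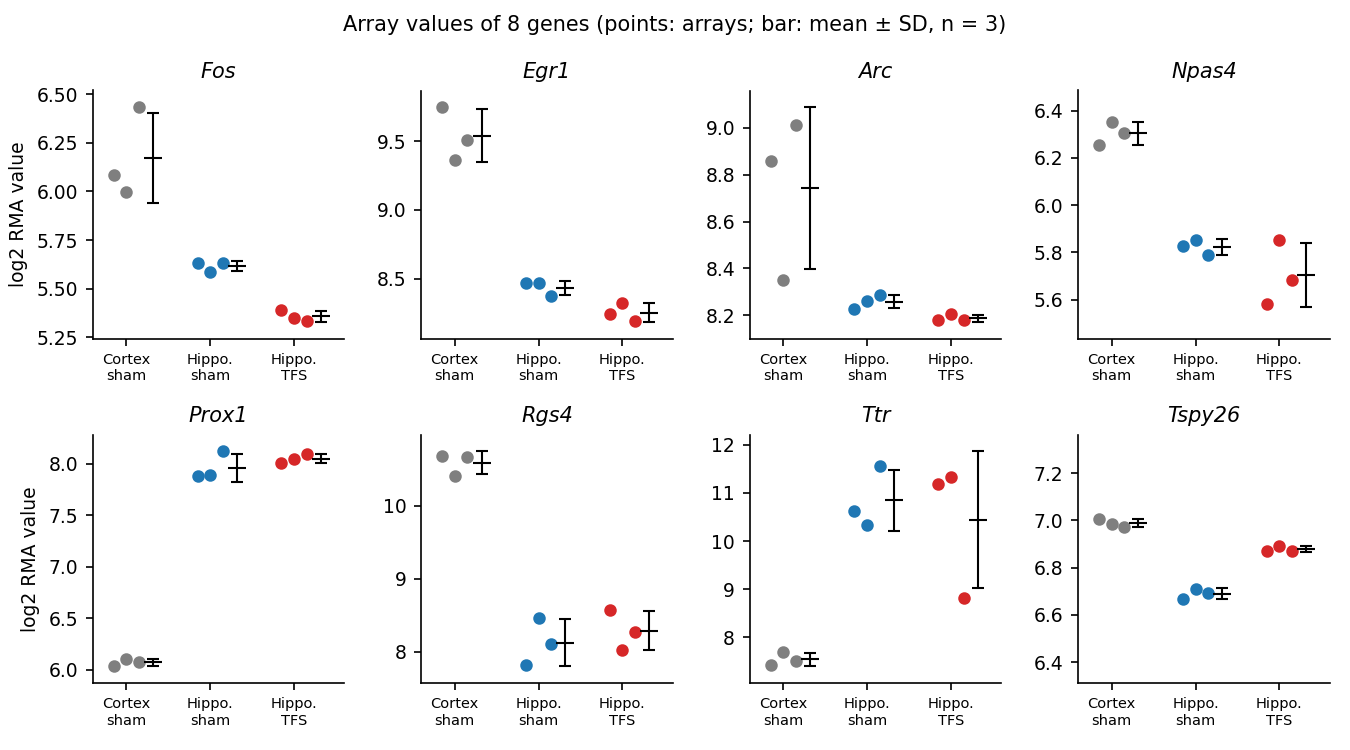
Log2 RMA values of 8 genes on each array, by group (points), with the mean and SD of 3 arrays (bars); the vertical axes differ between panels and do not start at 0. Fos and Egr1 lay lower in TFS than in sham hippocampus on every array without passing the test, and Ttr was 8.82 on TFS array 3 and 10.3 to 11.6 on the other hippocampal arrays.

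Markers of the hippocampal fields set the regions apart. Of 25 CA1 to CA3 field genes 11 were higher and 1 lower in hippocampus, and 13 were higher and 1 lower when adjusted over the list alone. The list median was 0.21 (camera adjusted p = 3.78e-05, and adjusted p = 0.131 with an estimated correlation). The kainate receptor subunit Grik4 differed by 0.97, Nrip3 by 1.29 and Fibcd1 by 1.26. Of 18 dentate gyrus genes 6 were higher and 1 lower, and 6 and 2 when adjusted over the list alone (median 0.12, adjusted p = 0.0153, and adjusted p = 0.490 with an estimated correlation). Beside Prox1 they included the synaptic protein gene C1ql2 at 1.35 and Dock10 at 1.53. Wfs1, a CA1 marker, differed by 0.20 and did not pass (adjusted p = 0.387). Of 41 cortical layer genes 15 were lower and 6 higher in hippocampus, and 17 and 7 when adjusted over the list alone (median -0.16, adjusted p = 4.46e-04, and adjusted p = 0.131 with an estimated correlation). Lamp5 differed by -1.49 and the transcription factor Tbr1 by -1.20. All 3 hippocampal arrays lay on the tested side for each of these lists.

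Among interneuron and peptide genes, more passed as lower than as higher in hippocampus. Of 29 interneuron markers 8 were lower and 2 higher, and 10 and 2 when adjusted over the list alone (median -0.04, adjusted p = 0.0061, and adjusted p = 0.542 with an estimated correlation; adjusted p = 0.105 without hippocampal array 3, the highest of a range from 7.13e-04). The peptide gene Vip was 6.98 ± 0.011 (SD, n = 3) in cortex and 5.96 ± 0.070 (SD, n = 3) in hippocampus, a log2 difference of -1.02 (adjusted p = 2.50e-05) between signals that both lie within the background range, and Sst, which encodes somatostatin, differed by -0.64 (adjusted p = 2.22e-04). Gad1 and Gad2 differed by -0.20 and -0.04 and did not pass (adjusted p = 0.147 and 0.631). Among 30 neuropeptide genes 10 were lower and 1 higher, and 10 and 2 when adjusted over the list alone (median -0.11, adjusted p = 0.0019, and adjusted p = 0.131 with an estimated correlation). The peptide precursor Vgf differed by -0.43 and the synapse organiser Cbln2 by -1.22. Presynaptic vesicle genes had 8 of 26 members lower and 2 higher, and 12 and 3 when adjusted over the list alone (median -0.12, adjusted p = 0.0049, and adjusted p = 0.542 with an estimated correlation). The fusion protein gene Stx1a differed by -0.96 and the calcium sensor Syt2 by -1.22. Striatum markers had 5 of 20 members lower and 2 higher, and 6 and 3 when adjusted over the list alone, with Arpp21 at -0.73 (median -0.14, adjusted p = 0.0283, and adjusted p = 0.662 with an estimated correlation). This list did not pass in the paired fit (adjusted p = 0.0734) or without cortical array 2 (adjusted p = 0.204), over a range of 0.0069 to 0.247.

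Several immediate early and clock genes had lower values in sham hippocampus than in sham cortex. Of 24 immediate early genes 11 were lower and 1 higher, and 14 and 1 when adjusted over the list alone (median -0.28, adjusted p = 7.19e-05, and adjusted p = 0.435 with an estimated correlation). Egr1 was 9.54 ± 0.19 (SD, n = 3) in cortex and 8.43 ± 0.051 (SD, n = 3) in hippocampus, a log2 difference of -1.10 (SE 0.09, adjusted p = 3.70e-04). Dusp1, a phosphatase for MAP kinases, differed by -1.28 (adjusted p = 0.0014) and Npas4 by -0.48 (adjusted p = 0.0028). For Fos the difference was -0.55 (SE 0.10, adjusted p = 0.0109), which did not pass in the 6 sham arrays without pairs (adjusted p = 0.0572) or with them (adjusted p = 0.0781, over a range of 0.0012 to 0.0781). Arc differed by -0.48 and did not pass (adjusted p = 0.0799), but passed without cortical array 2 (adjusted p = 4.31e-04, over a range of 4.31e-04 to 0.315). Of 21 circadian clock genes 10 were lower and 0 higher, and 12 and 1 when adjusted over the list alone (median -0.17, adjusted p = 3.24e-05, and adjusted p = 0.131 with an estimated correlation). The clock transcription factors Npas2, Hlf and Bmal1 differed by -0.93, -0.81 and -0.30. All 3 hippocampal arrays lay on the lower side for both lists.

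Lists of oligodendrocyte, vascular, choroid plexus and meningeal markers also differed with camera's preset correlation, and none of them with an estimated one. The astrocyte and microglia lists passed with neither. For comparison with the counts of members, 12.4% of all tested genes passed the limma test. Of 24 oligodendrocyte and myelin markers 4 were higher and 0 lower in hippocampus, and 17 and 0 when adjusted over the list alone (median 0.39, adjusted p = 1.25e-06, and adjusted p = 0.542 with an estimated correlation). Hapln2 of myelinated nodes differed by 0.34, the myelin gene Mobp by 0.44 and Mbp by 0.23 (adjusted p = 8.27e-04, 0.0183 and 0.0734). Mobp did not pass without cortical array 1, hippocampal array 2 or hippocampal array 3 (adjusted p = 0.0666, 0.0715 and 0.0692) or in the paired fit (0.0830), over a range of 0.0017 to 0.0986, and Mbp passed without cortical array 3 (adjusted p = 0.0043, over a range of 0.0043 to 0.211). Oligodendrocyte precursor markers had 5 of 19 members higher and 0 lower, and 7 and 0 when adjusted over the list alone (median 0.11, adjusted p = 4.38e-04, and adjusted p = 0.148 with an estimated correlation). Vcan, a matrix proteoglycan, differed by 0.28. Choroid plexus and ependyma markers had 5 of 21 members higher and 0 lower, and 10 and 0 when adjusted over the list alone (median 0.28, adjusted p = 4.38e-04, and adjusted p = 0.662 with an estimated correlation), with Tmem212 at 0.38. Meningeal and fibroblast markers had 8 of 22 members lower and 0 higher, and 14 and 0 when adjusted over the list alone (median -0.42, adjusted p = 5.31e-06, and adjusted p = 0.585 with an estimated correlation). Aldh1a2, an enzyme of retinoic acid synthesis, differed by -0.94, a call lost without hippocampal array 1 or 3 (adjusted p = 0.0504 and 0.0505) and in the paired fit (0.0511), over a range of 0.0071 to 0.0511. Endothelial and pericyte markers had 4 of 29 members lower and 0 higher, and 7 and 0 when adjusted over the list alone (median -0.16, adjusted p = 1.65e-04, and adjusted p = 0.360 with an estimated correlation), with the peptidase gene Anpep at -0.22. For the 5 lists with members counted here the 3 hippocampal arrays lay on the tested side. Gfap at 0.54 (adjusted p = 0.136), Aif1 at -0.02 (adjusted p = 0.636), Hbb at -0.13 (adjusted p = 0.805) and Slc17a7 at 0.16 (adjusted p = 0.156) did not pass, but Slc17a7 passed without cortical array 3 (adjusted p = 0.0106, over a range of 0.0106 to 0.372). The signals of Aif1 and Hbb lay within the background range in both regions.

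With camera's preset correlation 14 of 38 lists passed between the regions, 5 higher and 9 lower, with an estimated correlation 0, and with fry 13. The fry calls leave out choroid plexus (adjusted p = 0.108), meningeal (0.0507) and striatum markers (0.0557) and add glutamate genes, tested higher (0.0070), and later activity-regulated genes, tested lower (0.0387). Without hippocampal sham array 2 the count of genes was 1285. Arrays of the regions did not overlap for 3742 genes, 24.1%, where chance gives at most 10%.

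**Figure D3:**
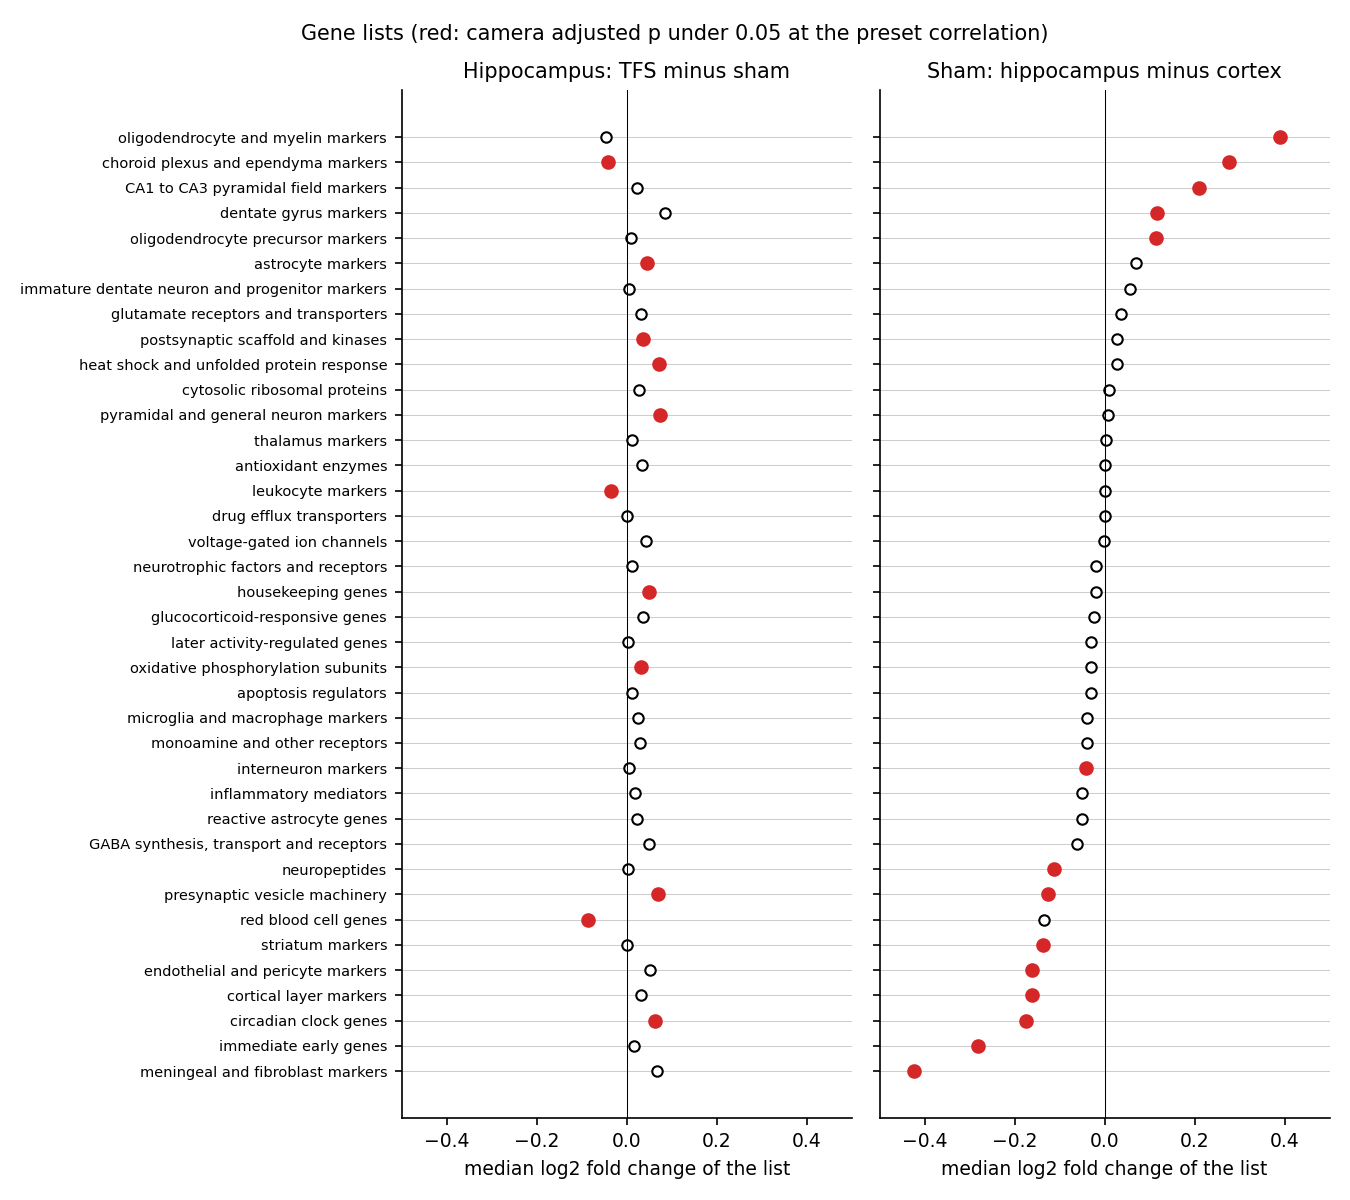
Median log2 fold change of 38 gene lists, TFS minus sham hippocampus on the left and sham hippocampus minus sham cortex on the right; the list called monoamine and other receptors holds serotonin, dopamine and noradrenaline receptors and transporters with some others. Red points passed camera with its preset correlation, 11 on the left and 14 on the right, and 0 on either side passed with an estimated correlation; after quantile normalization the left medians of postsynaptic, oxidative phosphorylation and housekeeping genes fall below 0.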

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

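The share of higher genes after quantile normalization, the same share without hippocampal sham array 1 and the correlations with Ttr are tests chosen only after the result was seen.

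An array row with no listed gene, TC0100001637.rn.1, was the 1 transcript cluster that differed after TFS when every row was tested, a signal outside the named genes. It measured 6.93 ± 0.16 (SD, n = 3, log2) in sham and 5.74 ± 0.059 (SD, n = 3) in TFS hippocampus, a difference of -1.18 (SE 0.088, limma adjusted p = 0.0419 over 34421 rows), with all 3 TFS arrays below all sham arrays. Both levels lie within the range of negative control probe sets, 95% of which had a mean under 7.57. Cortex of sham rats had 6.88 ± 0.11 (SD, n = 3). Without hippocampal sham array 1, 2 or 3 the adjusted p was 0.129, 0.0633 and 0.378, without TFS array 1, 2 or 3 it was 0.442, 0.409 and 0.199, and in a fit of the 6 hippocampal arrays 0.370; after quantile normalization it was 0.0284, the lowest of these alternatives. No explanation of this row was tested.

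More genes were higher than lower after TFS at an unadjusted p under 0.05, 679 against 126, among named genes; over every row, named or not, more were lower, 983 against 736. The share of higher genes dropped from 84.3% to 56.8% (56.844 in full) after quantile normalization, so a difference in the spread of signals between arrays may account for most of the excess. The excess remained without hippocampal sham array 1, where 78.5% were higher. Splits of the 6 arrays that mix TFS and sham had 56.3% to 78.2% of such genes on one side. A share of that size therefore cannot decide what part that array plays. The 6 arrays allow 10 splits, too few for a share under 0.05: the real split gave 805 genes, 3 splits gave as many or more with the real one included, and the highest of the others gave 952. For genes past an adjusted p under 0.05 the 10 splits are too few as well: the real split and all others gave 0, so that 10 splits gave as many. A biological shift of brightly expressed genes by TFS stays open, as untested apart from these values.

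Sham arrays of one number deviated together in cortex and hippocampus. After quantile normalization and removal of the trend with mean signal the correlations across genes were 0.366, 0.181 and 0.240. That they remained argues against the spread of signals as the whole source. The highest among unlike numbers was 0.0516, but taking deviations from group means by itself pushes those values down. Without these corrections, TFS and sham hippocampal arrays of unlike numbers also reached 0.264. That cortex and hippocampus of one number come from one rat cannot be told apart from shared handling: 1 of the 6 possible pairings had a mean correlation as high as 0.290 (the next had 0.175), and 6 pairings cannot give a share under 0.05. A shared rat and a shared day of dissection or hybridisation both stay open, since the labels give neither.

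Ttr varied over the 6 hippocampal arrays, with 10.6, 10.3 and 11.6 on the sham arrays and 11.2, 11.3 and 8.82 on the TFS arrays. A candidate explanation is a differing amount of choroid plexus in the dissected tissue: the other 20 listed genes had a median Pearson correlation of 0.874 with Ttr around the group means, at the percentile of 100 among 10000 random gene lists of like signal, 95% of which lay below 0.376. The median Spearman correlation was 0.829, and 1 of the 36 orders of Ttr within the groups gave a value as high for each measure (permutation p = 0.0278, one-sided and the smallest they can give). Without TFS array 3 and sham array 2, the arrays farthest from the median once Ttr is centred on its group means, the median Pearson correlation was 0.725, and 14 of the 20 genes had their lowest hippocampal value on TFS array 3. A change of choroid plexus by TFS stays open as untested, but the other TFS arrays do not share the low value.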

How the results depend on the processing

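The block over the 6 sham arrays, leaving out both sham arrays numbered 1, the genes without shared values and the list tests after quantile normalization were chosen only after the results were seen. After TFS the count of genes stayed at 0 in every fit except 3 at an unadjusted p under 0.05 with a 1.5-fold difference, 1 lower over every row, 1 higher with array weights (Tspy26, 0.18, adjusted p = 0.0380, against 0.134 to 0.912 over 12 other refits) and 1 lower without both sham arrays numbered 1 (Sncg, -1.23, adjusted p = 0.0082, over a range of 0.0082 to 1). Genes at an unadjusted p under 0.05 numbered 1719 over every row (736 higher, 983 lower), 526 after quantile normalization, 1548 with array weights, 373 without shared values, and 574 to 810 leaving out 1 array. The 11 lists became 0 with an estimated correlation, 0 with fry, 6 with 6 arrays, 7 after centring, 0 after quantile normalization, 0 without shared values (fewer genes tested), 4 without both sham arrays numbered 1, and 2 to 10 leaving out 1 array. The medians of postsynaptic genes (-0.0020) and oxidative phosphorylation subunits (-0.013) turned negative after quantile normalization, and that of choroid plexus markers turned to 0.082 without TFS array 3, in a range of -0.12 to 0.082 leaving out 1 array. Between the regions the count was 428 at an unadjusted p under 0.05 with a 1.5-fold difference, 1211 with 6 arrays, 982 with the paired block over 6 sham arrays, and 1285 to 2183 leaving out 1 array; genes at an unadjusted p under 0.05 numbered 6351 over every row, and 0 lists passed with an estimated correlation. The first component held 82.8% over the 1000 genes of largest variance. Except where fewer genes or arrays were tested, the cause was not tested.

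TFS arrays were not taken to pair with sham arrays, so a replicate block over 9 arrays is a check only. After TFS it gave 0 genes, 937 at an unadjusted p under 0.05 and 9 lists. Between the regions it gave 1925 genes and 14 lists. A random block gave 0 genes after TFS and 2077 between the regions. The paired block over the sham arrays ended the call of 1 list, striatum markers. In 12 refits after TFS, array weights not among them, 2206 of 2207 values of 184 named genes kept their side of the threshold and 1, Sncg, passed; between the regions 1974 of 2223 values did, 215 fell below it in 46 of 171 genes and 34 passed in 17, with 0 reversed. Of 570 list values after TFS 454 kept their side, 103 were weaker, 10 stronger and 3 reversed. The weaker and reversed values all belong to lists called in the main fit, while lists without a call mostly stayed without one. The pooled count therefore does not show the calls to be stable. Between the regions 574 of 608 values kept their side, 21 were weaker and 13 stronger.

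Signal over background was at least 3.67 log2 units on every array. On simulated data with 200 changed genes and independent noise, 46.6% of changes of 0.2 log2 units and 94.4% of changes of 0.6 were recovered in the TFS contrast. The simulation shifted array signals, so it does not show that changes of transcript were within reach for genes in the background range. Fewer changed genes, for which the adjusted threshold is stricter, were not simulated.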

Other observations

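Between the regions, receptor and channel genes differed in both directions, and their lists did not pass with camera. The comparisons of splits by array number, the block over the 6 sham arrays, leaving out both sham arrays numbered 1 and the list tests after quantile normalization were chosen only after the results were seen. Of 27 glutamate receptor and transporter genes 9 were higher and 5 lower in sham hippocampus than in sham cortex, and 11 and 8 when adjusted over the list alone (median 0.04, camera adjusted p = 0.177), and the list passed fry, tested higher (adjusted p = 0.0070). The AMPA receptor subunit Gria1 differed by 1.19 and the metabotropic receptor Grm4 by -0.41. Of 18 GABA genes 3 were higher and 4 lower, and 4 and 6 when adjusted over the list alone (median -0.06, adjusted p = 0.403). The GABA-A receptor subunits Gabrb1 and Gabra5 differed by 0.80 and 0.99, and Gabra3 and Gabrd by -1.11 and -0.87; Gabra5 did not pass in the paired fit (adjusted p = 0.0563, over a range of 6.17e-04 to 0.0563). Among 31 voltage-gated ion channels 7 were higher and 7 lower, and 10 and 10 when adjusted over the list alone (median -8.5e-04, mean 0.03, tested higher, adjusted p = 0.740). The sodium channel subunit Scn3b differed by 1.22 and the calcium channel Cacna1h by 0.72. Among 39 serotonin, dopamine, noradrenaline and other receptors and transporters 7 were higher and 7 lower, and 9 and 9 when adjusted over the list alone (median -0.04, mean 0.05, tested lower, adjusted p = 0.848). The serotonin receptor Htr1a differed by 1.24 and the nicotinic receptor subunit Chrna4 by -1.06. Neurotrophic factors and receptors had 5 of 26 members higher and 4 lower, and 7 and 6 when adjusted over the list alone, with Fgfr1 at 0.87 (median -0.02, mean 0.02, tested higher, adjusted p = 0.740). Postsynaptic genes had 5 of 25 higher and 9 lower, and 7 and 9 when adjusted over the list alone, with Prkca at 0.58 and Cacng3 at -0.94 (median 0.03, mean -0.07, tested lower, adjusted p = 0.848). Of 11 drug efflux transporters 1 passed, Abcb1b at 0.78, which was also the 1 that passed when adjusted over the list alone (list median 0, mean 0.06, adjusted p = 0.740). Each gene named here lay on its side on all 3 hippocampal arrays against all 3 cortical ones.

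Later activity-regulated genes had 3 of 26 members higher and 5 lower, and 3 and 6 when adjusted over the list alone, with Scg2 at 0.50 (median -0.03, camera adjusted p = 0.365, fry adjusted p = 0.0387 for lower). General neuron markers had 5 of 20 higher and 2 lower, also when adjusted over the list alone, with the transcription factor Neurod2 at 0.64 (median 0.0070, adjusted p = 0.574). Immature dentate neuron and progenitor markers had 6 of 21 higher and 2 lower, also when adjusted over the list alone, with Neurod1 at 0.86 and Hopx at -0.53 (median 0.06, adjusted p = 0.102; adjusted p = 0.0285 without cortical array 2, the lowest of a range up to 0.210, and at least 0.448 with an estimated correlation). Thalamus markers had 5 of 26 higher and 3 lower, and 5 and 6 when adjusted over the list alone, with Lhx9 at 0.79 (median 0.0021, adjusted p = 0.808). Astrocyte markers had 2 of 23 higher and 0 lower, and 1 and 0 when adjusted over the list alone (median 0.07, adjusted p = 0.0582; 0.0013 without cortical array 2 and 0.0499 without hippocampal array 3, over a range of 0.0013 to 0.303; at least 0.336 with an estimated correlation). Microglia markers had 3 of 24 lower and 0 higher, also when adjusted over the list alone, but RT1-Da at -0.57, Cd74 at -0.58 and Cd68 at -0.28 did not pass in the paired fit (adjusted p = 0.110, 0.0970 and 0.170, the highest of their ranges but for Cd74, which reached 0.110). Without hippocampal array 2 none of the 3 passed (adjusted p = 0.0628, 0.0909 and 0.0949); Cd74 did not pass without cortical array 1 or 2 or hippocampal array 1 or 3 (0.0560, 0.0603, 0.0591 and 0.0578), nor Cd68 without cortical array 2 or 3 or hippocampal array 3 (0.0864, 0.0965 and 0.110). As a list microglia markers did not pass (median -0.04, adjusted p = 0.178; 0.0476 without cortical array 1 and 0.0341 without cortical array 3, over a range of 0.0341 to 0.972; at least 0.747 with an estimated correlation). Oxidative phosphorylation subunits had 1 of 38 lower, Ndufs3 at -0.14, and 0 when adjusted over the list alone. Ndufs3 did not pass in the 6 sham arrays without pairs (adjusted p = 0.0938) or with them (0.0537) or without cortical array 3, hippocampal array 1 or hippocampal array 2 (0.0635, 0.0702 and 0.0867), over a range of 0.0106 to 0.0938. The oxidative phosphorylation list did not pass (median -0.03, adjusted p = 0.0878; 0.0081 without cortical array 1, 0.0351 without hippocampal array 2 and 0.0324 without hippocampal array 3, over a range of 0.0081 to 0.707; at least 0.127 with an estimated correlation). Ribosomal proteins had 0 of 40 past the limma test, 0 at an unadjusted p under 0.05 and a median of 0.0090 (adjusted p = 0.596; 0.0179 without cortical array 2, over a range of 0.0179 to 0.810; at least 0.848 with an estimated correlation). Glucocorticoid-responsive genes (adjusted p = 0.848, Bcl6 at 0.50), apoptosis regulators (0.848, Bok at 0.33), antioxidant enzymes (0.848), heat shock genes (0.778), inflammatory mediators (0.115), reactive astrocyte genes (0.671, Amigo2 at 0.31), red blood cell genes (0.808), leukocyte markers (0.848) and housekeeping genes (0.740) did not pass either.

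After TFS the other lists did not pass with camera's preset. Adjusted p was 0.361 for ion channels (median 0.04), 0.851 for neurotrophic genes (median 0.01, tested lower), 0.841 for glucocorticoid-responsive genes (median 0.04), 0.109 for antioxidant enzymes (median 0.03) and 0.773 for ribosomal proteins (median 0.03). It was 0.428 for interneuron markers (median 0.0046, tested lower), 0.904 for microglia markers (median 0.03), 0.0916 for oligodendrocyte markers (median -0.05), 0.686 for oligodendrocyte precursor (median 0.0084, tested lower) and endothelial markers (median 0.05), and 0.422 for meningeal markers (median 0.07). It was 0.0671 for dentate gyrus (median 0.08), 0.910 for CA field (median 0.02), 0.865 for cortical layer (median 0.03) and 0.910 for thalamus markers (median 0.01, tested lower). It was 0.686 for striatum markers (median 7.6e-04, tested lower), 0.686 for immature neuron markers (median 0.0053, tested lower), 0.20 for neuropeptides (median 0.0016, tested lower) and 0.950 for serotonin, dopamine and noradrenaline genes (median 0.03). Leaving out 1 array brought some of these past the threshold: ion channels without sham array 2 (0.0376, in a range of 0.0376 to 0.924), ribosomal proteins (0.0444, to 0.945), interneuron markers (0.0364, to 0.790) and dentate gyrus markers (0.0085, to 0.409) without sham array 3, and antioxidant enzymes (0.0427, in a range of 0.0216 to 0.763), oligodendrocyte markers (0.0025, to 0.658) and meningeal markers (1.37e-04, to 0.983) without TFS array 3. These are preset calls: with an estimated correlation the lowest adjusted p over the refits was 0.689, 0.859, 0.851, 0.396, 0.647, 0.859 and 0.806 in that order. Other refits with the preset also brought calls. Dentate gyrus markers passed after median centring (median 0.070, adjusted p = 0.0219) and antioxidant enzymes without a filter on signal (adjusted p = 0.0216). Oligodendrocyte markers passed without both sham arrays numbered 1 (adjusted p = 0.0321). By fry's mixed test, which asks for changes in either direction, glutamate and circadian clock genes passed (adjusted p = 0.0456 for both).

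The 6 sham arrays allow 10 splits, too few for a share under 0.05. The regional split called 1931 genes, 1 split with itself included called as many, and the highest other called 1. The regional split parts the arrays of each of the 3 numbers, as do 3 other splits, which called 0 genes and gave at most 335 at an unadjusted p under 0.05. The remaining 6 splits part 1 number only and gave up to 1876 such genes.

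Of 34421 array rows above the filter, 18187 carried no single listed gene; 761 of these passed between the regions, 403 higher and 358 lower in hippocampus. Olfactory receptors, 73 genes with a median signal of 2.76 of which 3 lay above the filter, had 0 genes past the limma test after TFS and 4 at an unadjusted p under 0.05, and 3 and 5 between the regions, in a fit of 22093 genes without a filter. Their arrays did not overlap for 6.85% of them, where chance gives 10% without shared values and less with them.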
